A study of Mus musculus with 12 samples.

How the data were processed

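Bone marrow cells were cultured with M-CSF and taken as macrophages on day 7, and RNA was extracted with TRIzol and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. This kit does not keep the strand of a transcript. The authors deposited a table of read counts per gene for 12 libraries and a summary of how alignment records were assigned. The deposited counts are whole, not normalised, and were made with featureCounts 1.6.0 against the Ensembl release 100 annotation of GRCm38, per the file headers. The header's command sets no strand, no counting of pairs as fragments and no counting of multiply aligned reads. FastQC, STAR and the build mm10 are named in the submitters' processing notes, with no versions. Totals of unmapped and of multiply aligned records were even in all 12 libraries, and whether mates were counted separately is not given in the sources used here. Low counts were mostly even too. Those of Ly6c2 were even in every library other than old replicate 6 (435), and those of Gm47283 in every library other than young replicate 6 (511). Those of Bmpr1a were even in young and mixed in old libraries. This points to mates counted separately for many fragments. Counting mates separately would double the counts of a fragment, so totals are counts of alignment records and not of independent molecules.

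Table columns were matched to the labels by the letter of the group and the replicate number, and no column was left unused. Of 55401 gene IDs, 55141 were given a symbol by a reference table of gene names, and the 260 others held 0.0044% of counts. A count was present for 24139 genes. Column sums equalled the assigned totals of the summary in every library. Libraries were compared pair by pair, and the chi-square per gene between 2 libraries ranged from 5.17 to 184, so no pair agreed within sampling noise and all 12 were kept.

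Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust fitting, TMM factors and edgeR's own low-count filter, which left 12620 genes holding 99.9% of counts. The model held the group alone and all 12 libraries, and a positive log2 fold change means higher in old. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 21.7%, and the median standard error of a log2 fold change was 0.13 (0.11 for the 9424 genes of at least 5 CPM). CPM were computed here from the counts with TMM factors. On counts simulated from these means and library sizes for old against young with 12620 genes, the test recovered 0% of genes changed 1.2-fold, 42% of those changed 1.5-fold, 70% of those changed 2-fold and 98% of those changed 4-fold, and 6 of 111 calls were false. Each gene was drawn independently, while genes of the real libraries move together, so these rates may not carry over to the real counts.

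Fixed lists of genes (37) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. In addition to the count over all genes, each list was adjusted over the list alone, with no adjustment over the lists. The median, mean and camera direction of a list differed in sign for 7 lists, none of them called. Library composition was tested by exact permutation over the 924 assignments of the 12 libraries, with adjustment over 5 measures. A limit for a count of 0 was set at 3 counts of a library's total. Such limits cover counting error only, and they are too low where 1 fragment gives 2 counts. Python 3.11.15 with SciPy 1.17.1 was used for these tests.

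The genes named were set by a rule. It took genes past the threshold with a mean of at least 5 CPM, up to 10 rising and 10 falling, and as fewer than 10 genes passed, those of at least 5 CPM with the lowest p up to 10. It also took the 5 of lowest p in each direction among genes past the threshold, up to 4 members past it per list or else the most abundant member, sex-linked and substrain genes, and Adgre1, Csf1r, Itgam, Cd68 and Lyz2. Genes outside the rule were chosen after their values were seen: Cpne8, Marco, Clec1a, Cd4, Gm47283, Pmvk, Cd209a, Id1, Id3, Smad6, Ly6c2, Mki67, Cd34 and the BMP target genes of the closing section. The design, lists, rule and most alternatives were fixed before the data were examined. Alternatives were other scalings (RLE, upper quartile, library size), 2 other filters, DESeq2 1.42.0, limma voom with and without quality weights, fitting without robust estimation, a replicate block, 1 surrogate variable from sva 3.50.0, a fold threshold of 1.2, other p thresholds and each library left out in turn. Leaving out young replicate 6, old replicate 2 and old replicate 3 together, a cell cycle covariate, and a term for replicate numbers 4 and 5, were chosen after seeing the data. To see how often other groupings give as much, 100 of the 462 splits of the libraries into 6 and 6, the real one included, were fitted again. One gene's values are not reported here. The single-cell part of the study was not analysed here.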

Results

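Bulk RNA sequencing was performed on bone marrow derived macrophages from mice of the C57BL6 background, cells grown out of bone marrow with macrophage colony-stimulating factor (M-CSF) and taken after 7 days in culture. The 12 libraries fell into a young group of 6, from animals aged 8 weeks, and an old group of 6, from animals aged 12 months. Total assigned counts per library ranged from 22.2 to 25.2 M in the young group and from 19.3 to 22.4 M in the old group (1 M is 1000000 counts). The labels call the libraries biological replicates without saying whether each came from a separate animal, so p-values measure the spread between these 12 libraries. No library of this set was labelled as exposed to nanoparticles, although the series as a whole concerns macrophages that meet nanoparticles.

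The first question was which genes differ between young and old macrophages. Bmpr1a, a type I receptor for bone morphogenetic proteins (BMPs), was nearly silent in young macrophages and rose 17.5-fold in old ones, from 0.786 ± 0.321 CPM (SD, n = 6) to 13.8 ± 1.71 CPM (SD, n = 6). Gdf3, a ligand of the transforming growth factor beta superfamily, rose 2.10-fold, from 57.6 ± 9.41 to 121 ± 21.6 CPM (SD, n = 6 each). For both genes every old library lay above every young library. No gene passed the threshold in the lower direction. Of the 12620 genes tested, these were the 2 that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. The log2 fold change of Bmpr1a was 4.13 with a standard error of 0.22, and its edgeR adjusted p was 5.3e-07. That of Gdf3 was 1.07 with a standard error of 0.13, and its edgeR adjusted p was 0.011. Bmpr1a (ENSMUSG00000021796) spans positions 34410734 to 34503341 on the minus strand of chromosome 14 in GRCm38, and Gdf3 (ENSMUSG00000030117) spans positions 122605403 to 122610087 on the minus strand of chromosome 6. The counts cover the exons of each gene as a whole, so no exon or transcript form was resolved. At an unadjusted p below 0.05 there were 690 genes, 407 higher and 283 lower in old macrophages, against 631 for chance alone. Complete separation of the groups was seen for 26 genes, where chance alone gives 27.3. The count at an unadjusted p below 0.05 was 1612 without old replicate 2, 438 without old replicate 4, 315 without old replicate 6, 364 without young replicate 5, and 2302 with young replicate 6 and old replicates 2 and 3, the libraries with the highest cell cycle levels, left out together. DESeq2 called 15 genes on the same counts. With the 3 libraries left out 3 genes passed, Bmpr1a among them, and Gdf3 had a log2 fold change of 0.96 and an edgeR adjusted p of 0.12. Without young replicate 4 these were 1.05 and 0.057.

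**Figure D1:**
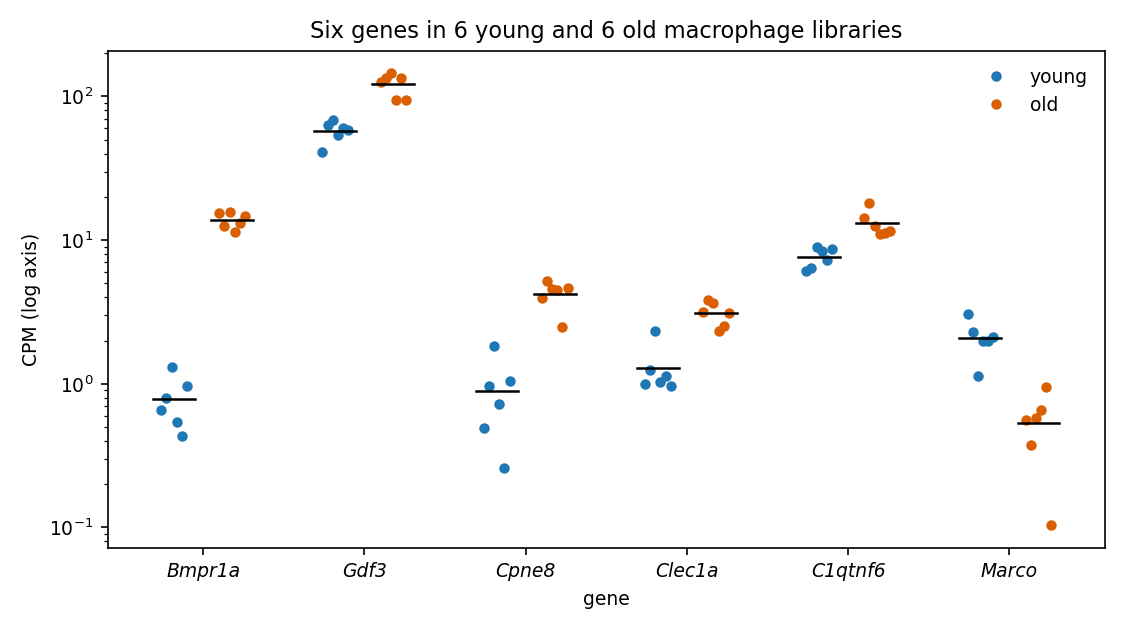
CPM of 6 genes (horizontal axis) in each of the 12 libraries on a log axis, with young libraries in blue, old libraries in orange and the group mean as a black line. Bmpr1a lay between 0.433 and 1.31 CPM in young libraries and between 11.5 and 15.6 CPM in old ones, and Bmpr1a and Gdf3 are the 2 genes of the 6 that passed the test.

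The genes of at least 5 CPM with the next lowest p-values did not pass the threshold in the main test. C1qtnf6 was at 7.63 ± 1.22 CPM in young and 13.1 ± 2.69 CPM in old libraries (SD, n = 6 each). Arhgef18, a guanine nucleotide exchange factor, was at 11.4 ± 3.12 and 20.5 ± 4.95 CPM, and Slc24a5 was at 7.95 ± 1.79 and 12.0 ± 1.87 CPM. Tnfsf13, which encodes the cytokine APRIL, was at 7.22 ± 2.44 and 12.2 ± 1.33 CPM, while its neighbour Tnfsf12, which encodes TWEAK, was at 118 ± 9.83 and 95.8 ± 3.85 CPM. Cyp51, an enzyme of cholesterol synthesis, was at 54.1 ± 6.27 and 40.9 ± 3.44 CPM, and Chchd7 was at 22.6 ± 2.20 and 17.6 ± 2.23 CPM. Plxdc2 was at 87.2 ± 33.9 CPM in young and 37.4 ± 7.03 CPM in old libraries. Young replicate 6 held 21.3 CPM against 82.9 to 113 CPM in the other young libraries, and without it the edgeR adjusted p of Plxdc2 was 1.4e-04. Tnfsf12, Tnfsf13, Cyp51 and Slc24a5 overlap other annotated genes in counts made without strand, so their levels are uncertain. A further 3 genes were picked after their values were seen. Cpne8 was at 0.890 ± 0.551 CPM in young and 4.22 ± 0.931 CPM in old libraries, with an edgeR adjusted p of 0.071. Clec1a was at 1.28 ± 0.520 and 3.10 ± 0.586 CPM, with an edgeR adjusted p of 0.23. The scavenger receptor gene Marco was at 2.09 ± 0.618 CPM in young and 0.536 ± 0.283 CPM in old libraries, with no overlap between the groups and an edgeR adjusted p of 0.23. DESeq2 called 9 of these genes, Cpne8, Marco, Clec1a, C1qtnf6, Tnfsf12, Cyp51, Plxdc2, Arhgef18 and Tnfsf13, at adjusted p-values from 9.9e-08 for Cpne8 to 0.0496 for Tnfsf13. Of 27 alternatives followed, DESeq2 among them, Cpne8 was called in 9, Plxdc2 in 4 and C1qtnf6 in 3. Marco, Clec1a, Arhgef18 and Tnfsf13 were called in 2 each, and Cyp51 and Tnfsf12 in 1 each. Without a low-count filter edgeR called Cpne8 (adjusted p = 0.018) and Marco (0.046), and limma voom called Cpne8 (0.042 with and without quality weights) and, with quality weights, Plxdc2 (0.0064). Without young replicate 3 edgeR called Cpne8 (0.0078), Clec1a (0.0078) and Tnfsf13 (0.011). Cpne8 and C1qtnf6 were called with 1 surrogate variable (0.0090 and 0.015) and with the cell cycle covariate (0.010 and 0.020), and Cpne8 and Arhgef18 with the replicate block (0.047 and 0.037). Cd4, also picked after its values were seen and at 20.8 ± 10.0 and 11.4 ± 4.03 CPM, was called lower with the surrogate variable (0.015) and with the cell cycle covariate (0.024), against an edgeR adjusted p of 0.77 in the main test.

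The second question was whether groups of related genes differ with age. Genes of cholesterol synthesis lay lower in old macrophages, with a negative log2 fold change in all 23 tested members and a median of -0.26. Ribosomal protein genes (median -0.16, 1 of 51 positive), nuclear-encoded genes of oxidative phosphorylation (median -0.15, 1 of 53 positive) and cell cycle genes (median -0.30, 2 of 52 positive) also lay lower. Genes of the circadian clock lay higher, with a median of 0.11 and 15 of 17 positive. These were the 5 of 37 fixed lists called by limma's camera at its preset correlation. None of the 745 tested list members passed the threshold over all genes. The cholesterol synthesis list had a camera adjusted p of 6.3e-12, and adjusted p = 0.67 with an estimated correlation. The ribosomal list had a camera adjusted p of 5.4e-20, and adjusted p = 0.97 with an estimated correlation. The oxidative phosphorylation list had a camera adjusted p of 5.2e-12, and adjusted p = 0.99 with an estimated correlation. The cell cycle list had a camera adjusted p of 0.034, and adjusted p = 0.99 with an estimated correlation. The circadian list had a camera adjusted p of 0.035, and adjusted p = 0.67 with an estimated correlation. Single libraries stood apart in these lists too. Of the 51 ribosomal genes, 38 were highest of their group in young replicate 5 and 45 in old replicate 2, while 34 were lowest in young replicate 3 and 48 in old replicate 6. Of the 53 oxidative phosphorylation genes, 47 were highest in young replicate 6 and 47 in old replicate 2, and 39 were lowest in old replicate 6. Of the 23 cholesterol synthesis genes, 16 were highest in young replicate 6 and 16 in old replicate 2. In the same list 11 were lowest in young replicate 3, 10 in young replicate 5 and 10 in old replicate 6. No list call held with an estimated correlation, and limma's fry called 0 lists in its directional and 0 in its mixed form.

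Within the cholesterol synthesis list 3 genes passed when adjusted over the list alone and not over the lists, all lower in old libraries. Among them were Cyp51 and Pmvk, phosphomevalonate kinase, which was at 29.1 ± 4.22 and 22.2 ± 3.20 CPM in young and old libraries. The most abundant member, Srebf2, was at 179 ± 14.8 and 163 ± 14.8 CPM. Rpl10 was at 1591 ± 207 and 1466 ± 93.8 CPM, Atp5b at 615 ± 130 and 567 ± 57.9 CPM, Pcna at 292 ± 104 and 263 ± 34.2 CPM, and Tef at 104 ± 15.6 and 111 ± 13.8 CPM (young then old, SD, n = 6 each). The cell cycle list moved with single libraries. Its mean log2 CPM was 6.52 in young replicate 6, 5.83 in old replicate 2 and 5.29 in old replicate 3, and between 3.91 and 4.94 in the other libraries. Without young replicate 6 the cell cycle list turned to the upward direction, with a camera adjusted p of 0.41. It was not called without old replicates 1, 4, 5 or 6 either, at camera adjusted p-values of 0.13, 0.50, 0.32 and 0.27. It was called lower with young replicate 6 and old replicates 2 and 3 left out together (1.8e-08). That call decides nothing on age, since the libraries left out were those with the highest levels of this list, more of them old than young. The circadian list was not called without young replicate 6 (camera adjusted p = 0.23), young replicate 1 (0.055), old replicate 2 (0.096) or old replicate 4 (0.061), nor with those 3 left out together (0.37).

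**Figure D2:**
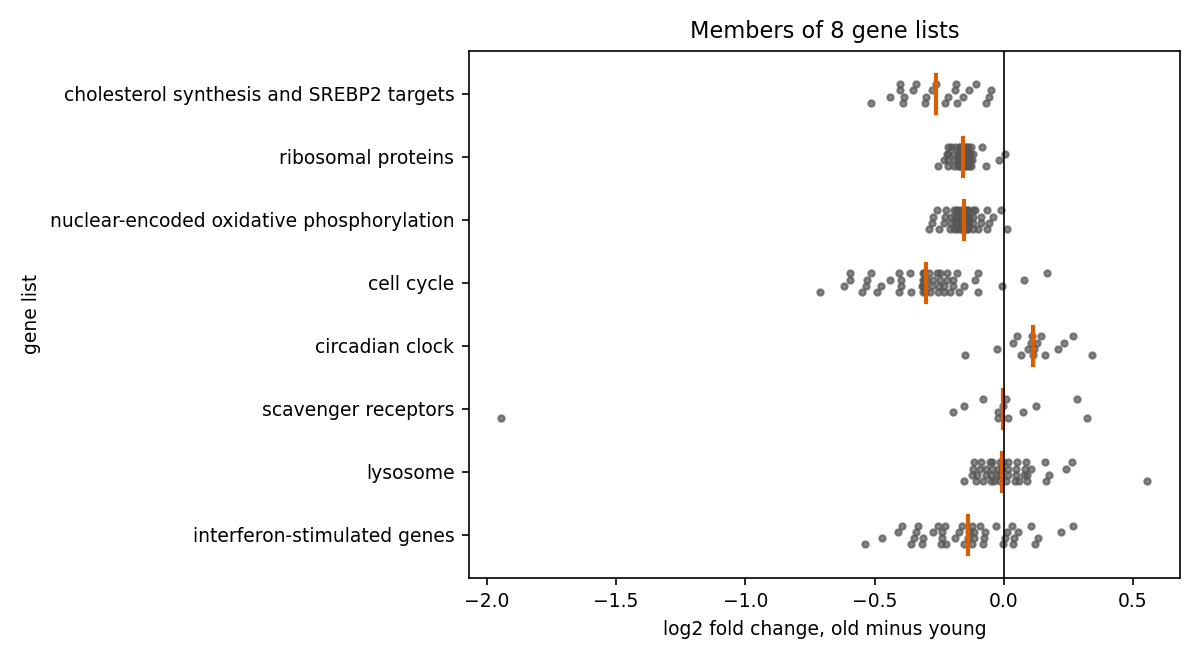
Log2 fold change, old minus young, of each tested member (grey point, horizontal axis) of 8 of the gene lists (vertical axis), with the median of each list as an orange bar; the vertical spread of points has no meaning. All 23 cholesterol synthesis members lie below 0, and Marco stands apart in the scavenger receptor list at -1.94.

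No list of genes for particle uptake and breakdown was called between the ages. Of 13 scavenger receptor genes 6 were positive (median -0.0039), and Marco was the 1 member that passed when adjusted over the list alone, at an edgeR adjusted p of 0.0010 within that list. Such a member was found in 3 of the 37 lists, with no adjustment over the lists. Cd68, the most abundant scavenger receptor gene, was at 2781 ± 370 and 2631 ± 148 CPM in young and old libraries. The 24 phagocytic receptor genes had a median of 0.01, with Sirpa at 2863 ± 207 and 2875 ± 281 CPM. The 33 genes of endocytosis and macropinocytosis had a median of -0.04, with Snx5 at 761 ± 130 and 778 ± 71.7 CPM. Lysosomal genes (45, median -0.01) were led by Psap at 29884 ± 6908 and 29779 ± 3577 CPM, and autophagy genes (28, median 0.0033) by Sqstm1 at 831 ± 39.1 and 817 ± 71.2 CPM. The 36 actin and adhesion genes had a median of -0.04, with Tmsb4x at 3926 ± 215 and 3620 ± 126 CPM.

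No list of immune activation genes was called in the main test. The medians were 5.2e-04 for 14 complement genes, 0.02 for 18 inflammatory cytokine and M1-associated genes, -0.07 for 22 chemokine and chemokine receptor genes and -0.10 for 15 alternative activation genes. They were -0.14 for 44 interferon-stimulated genes, 0.18 for 10 MHC class II genes, -0.02 for 19 MHC class I genes and 0.06 for 21 immediate early genes. The most abundant members were C1qb (3170 ± 1285 and 2952 ± 829 CPM), Marcks (443 ± 117 and 450 ± 73.0), Ccl9 (352 ± 36.1 and 373 ± 20.2), Trem2 (726 ± 88.5 and 672 ± 32.8), Bst2 (381 ± 174 and 299 ± 69.7), Cd74 (1236 ± 746 and 1397 ± 911), H2-D1 (4392 ± 1024 and 4328 ± 387) and Atf3 (396 ± 68.0 and 378 ± 56.0), young then old. The interferon-stimulated list differed between libraries of each group. Of its 44 genes, 43 lay above the other 5 young libraries in young replicate 5 and 42 lay below them in young replicate 6, while 43 lay above the other 5 old libraries in old replicate 4 and 30 lay below them in old replicate 2. This list was called lower in old libraries without young replicate 6 (camera adjusted p = 1.9e-05) or without old replicate 4 (0.0030), and over all 12 libraries with the cell cycle level as a covariate (1.3e-09), and MHC class I genes were called higher without young replicate 5 (0.043). Immediate early genes were called higher with young replicate 6 and old replicates 2 and 3 left out together (0.021). None of these calls held with an estimated correlation (adjusted p = 0.72 or higher), and other splits of the libraries called these lists often, the interferon list in 74 of 100.

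The lists for senescence and stress, and the remaining metabolic lists, were not called in the main test. Glycolysis genes, at a camera adjusted p of 0.094, were called lower in old libraries when any 1 of young replicates 1 to 5 was left out (0.022 to 0.044), though not with an estimated correlation (adjusted p = 0.86 or higher). In young replicate 6, 19 of the 22 genes lay above the other 5 young libraries, and without it the list turned upward (adjusted p = 0.90). The medians were -0.07 for 26 senescence genes, -0.10 for 27 DNA damage and p53 target genes, -0.12 for 11 mitochondrially encoded genes, -0.13 for 22 glycolysis genes, -0.01 for 26 lipid handling genes, -0.03 for 23 antioxidant genes, -0.01 for 26 unfolded protein and heat shock genes and -0.11 for 4 replication-dependent histone genes. Their most abundant members were Timp2 (545 ± 92.8 and 578 ± 94.1 CPM), Cdkn1a (254 ± 69.8 and 207 ± 29.99), mt-Co1 (5238 ± 641 and 6023 ± 842), Pkm (1472 ± 587 and 1302 ± 253), Gpnmb (13654 ± 2580 and 13546 ± 3059), Fth1 (19394 ± 1502 and 19034 ± 786), Hspa8 (1708 ± 263 and 1527 ± 102) and Hist1h1c (66.7 ± 12.7 and 74.8 ± 13.7), young then old.

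Both groups carried the transcripts of macrophages at high levels. Lyz2 was at 30704 ± 5454 and 30260 ± 3209 CPM, Csf1r at 4377 ± 974 and 4328 ± 655 CPM, Adgre1, which encodes F4/80, at 1190 ± 234 and 1266 ± 201 CPM, and Itgam at 170 ± 11.5 and 148 ± 9.85 CPM. The 20 macrophage identity genes had a median of -0.06. Marker lists of other cells were not called in the main test. Neutrophil markers were called higher with the replicate number as a block (camera adjusted p = 0.0026), with a term for numbers 4 and 5 (0.049), and without young replicate 5 (0.018) or old replicate 6 (8.1e-05). None of these calls held with an estimated correlation (adjusted p = 0.86 or higher), and 37 of 100 splits of the libraries called the list. Of its 12 genes, 10 were lowest of their group in young replicate 6 and 9 in old replicate 6, while 9 were highest in young replicate 5 and 9 in old replicate 4. The medians were 0.02 for osteoclasts (9 genes, Atp6v0d2 at 97.8 ± 22.3 and 144 ± 97.8 CPM), 0.37 for monocytes and myeloid progenitors (8, Irf8 at 342 ± 90.5 and 337 ± 46.3), 0.39 for neutrophils (12, Csf3r at 121 ± 46.2 and 136 ± 35.3), -0.02 for dendritic cells (9) and -0.19 for B and plasma cells (6, Blnk at 213 ± 13.4 and 206 ± 11.4). They were -0.27 for T and NK cells (2, Il7r at 122 ± 16.8 and 153 ± 77.5), 0.24 for mast cells, basophils and eosinophils (5, Kit at 7.77 ± 2.32 and 11.2 ± 5.19), 0.07 for erythroid cells and megakaryocytes (4, Tfrc at 75.7 ± 14.9 and 82.8 ± 44.4) and -0.05 for stromal and endothelial cells (7, Spp1 at 2318 ± 590 and 2172 ± 396). The dendritic cell gene Cd209a, at 1.32 ± 0.534 and 0.582 ± 0.268 CPM, passed when adjusted over the list alone, at an edgeR adjusted p of 0.048 within that list. That value was not adjusted over the lists.

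The third question was whether the libraries of the 2 groups differ in make-up. Old libraries held fewer assigned counts, 21.3 ± 1.09 M against 23.5 ± 1.18 M (SD, n = 6 each), and all 6 old libraries lay below the young mean. This was the 1 of 5 measures that passed a two-sided exact permutation test, with p = 0.0043 and a Benjamini-Hochberg adjusted p of 0.022. The share of alignment records assigned to genes was 71.7 ± 0.449% in young and 71.8 ± 0.563% in old libraries (exact permutation p = 0.85). The lower total is thus one of depth rather than of make-up. The labels name no batch, so handling that differed between the groups cannot be told apart from age. Mitochondrial genes took 1.48 ± 0.115% and 1.51 ± 0.0730% of counts (exact permutation p = 0.61), and the 100 most counted genes took 31.9 ± 1.46% and 31.7 ± 1.02% (exact permutation p = 0.88). Genes with at least 1 count numbered 17387 ± 106 and 17343 ± 174 (exact permutation p = 0.61). The adjusted p of each of these 4 measures was 0.88.

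Xist was at 350 ± 21.2 CPM in young and 389 ± 60.1 CPM in old libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 12 libraries. A count of 0 allows up to 0.119 to 0.155 CPM per library, for counting error alone, and more if mates were counted separately. Tsix, which overlaps Xist on the other strand, also had 0 counts. Of the genes that differ between C57BL/6 substrains, Nnt did not exceed 0.512 CPM in any library, Wdfy1 was at 14.9 ± 2.20 and 16.1 ± 1.93 CPM, Ide at 21.1 ± 8.08 and 22.8 ± 9.52 CPM and Fgfbp3 at 3.62 ± 0.821 and 2.94 ± 0.842 CPM. Entpd4 and its near-identical copy Entpd4b had at most 2 counts in a library, in counts that leave out reads with several alignments. The first principal component of log2 CPM held 43.9% of the variance and did not separate the age groups.

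**Figure D3:**
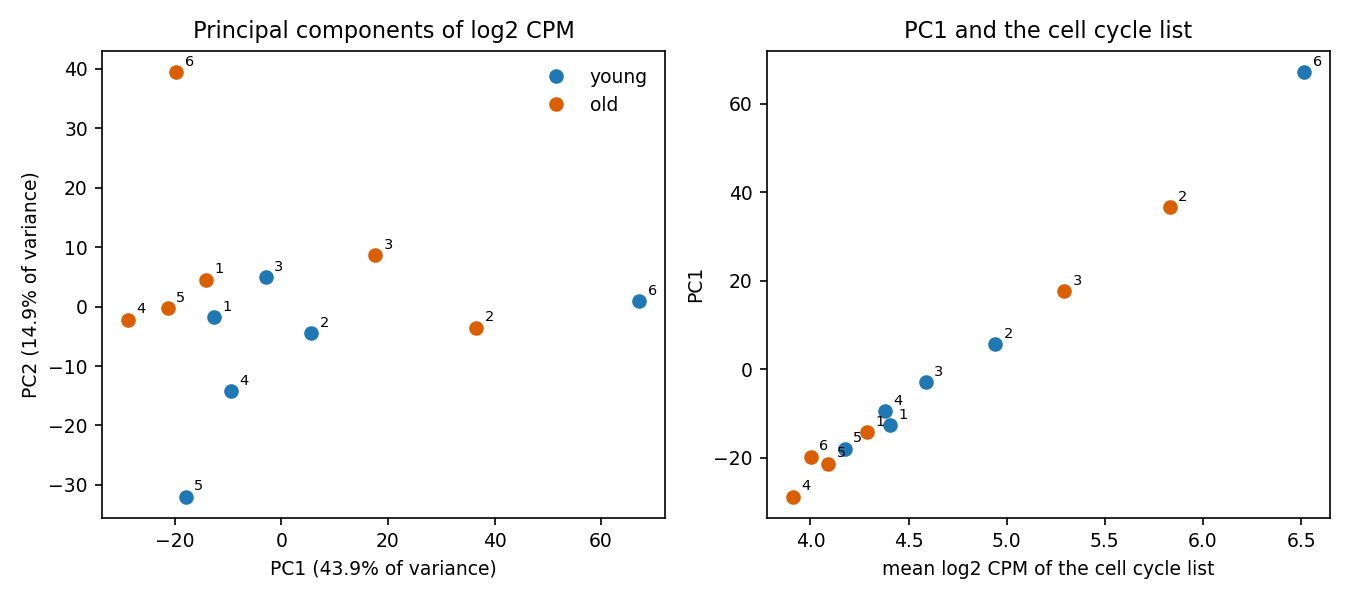
Left, the first and second principal components of log2 CPM for the 12 libraries; right, the first component against the mean log2 CPM of the cell cycle list, with young libraries in blue, old in orange and replicate numbers beside the points. Young replicate 6 lies farthest out on the positive side of the first component, followed on that side by old replicates 2 and 3, which are also the libraries with the highest cell cycle means.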

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

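All tests of explanations in this part were chosen after the results were seen. A library lying far outside the other 5 of its group was found for 27 values among 152 groups looked at, where chance gives about 1 in 20. With genes picked after their values were seen left aside, there were 20 values among 126 groups, against 6.3 by chance, and these values are not independent of each other. Young replicate 6 held 12 of the 27, and 8 of the 20. Its cell cycle mean of 6.52 log2 CPM lay above the 4.18 to 4.94 of the other young libraries, and Mki67, a proliferation marker, stood at 400.0 CPM against 52.5 to 163. Among targets of BMP signalling, 3 genes picked after their values were seen stood far above the other young libraries, with Id1 at 38.6 CPM against 0.353 to 1.14, Id3 at 196 CPM against 8.72 to 19.3 and Smad6 at 25.4 CPM against 0.606 to 1.77. Other targets did so less or not at all. Id2 stood at 226 CPM against 68.4 to 94.1, Smad7 at 5.34 CPM against 2.51 to 3.90, Bambi at 13.02 CPM against 9.18 to 11.1 and Hey1 at 0.647 CPM against 0.353 to 0.789. Pkm (2665 CPM), Atp5b (877 CPM) and Cdkn1a (389 CPM) were also higher than in the other young libraries. Csf1r (2524 CPM), Psap (16687 CPM), Snx5 (501 CPM) and Plxdc2 (21.3 CPM) were lower.

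What sets young replicate 6 apart is partly open, and no biological explanation was tested, since the design names no group that parts it from the other young libraries. Depth is argued against, since its total of 23.7 M counts lay inside the range of the other young libraries. Dilution by neutrophils, dendritic cells, lymphocytes, mast cells, erythroid or stromal cells is argued against. Each of their 7 marker lists was lower on average in this library, the highest by a mean log2 difference of -0.10. No upper bound (2 standard errors over members) lay above 0.80, a spread over genes of 1 library. These means hold only members past the low-count filter, 2 for T and NK cells. Some of those, such as Spp1 and Il7r, were high in every young library, so the means alone decide little. The members below the filter reached at most 0.647 CPM in this library (Xcr1). Dilution by immature myeloid cells or by cells with no marker list may play a part. Of the 20 macrophage identity genes, 90% lay below the mean of the other 5 young libraries. The progenitor gene Cd34, picked after its values were seen, stood at 59.7 CPM against 0.260 to 2.96. Its list, monocyte and myeloid progenitor markers, did not rise as a whole, with 3 of 8 members higher and 5 lower. The mean log2 difference of that list was -0.46, with a standard error over members of 1.02. F13a1 stood at 2.06 CPM against 17.3 to 40.3, Irf8 at 177 CPM against 343 to 452, and Kit at 8.33 CPM against 5.92 to 12.2. The identity genes did not fall by a like factor, with log2 ratios from -1.98 to 0.33 and near 0 for Cd68 (0.04), Itgam (-0.02) and Spi1 (-0.02), but immature myeloid cells can carry these transcripts too, so such cells and a change of state cannot be told apart.

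Bmpr1a was higher in all 6 old libraries. The 6 tested genes within 1 Mb had a median log2 fold change of 0.050, so no joint rise of the neighbouring genes was seen. Whether reads from a neighbouring gene add to Bmpr1a cannot be decided by this, since such reads need no rise of that gene. Glud1, 1 of the 6, had a mean of 280 CPM, against 13.8 CPM for Bmpr1a in old libraries. Stromal cells are argued against, since 8 abundant stromal transcripts summed to 0.616 CPM in old libraries, while Bmpr1a stood at 13.8 CPM. Among the 8 were Col1a1, Col1a2 and Sparc. An allele or insertion carried by the animals of one age group cannot be told apart from age, because counts hold no reads across the gene, and Nnt, at no more than 0.512 CPM in any library, says nothing about chromosome 14. A change with age stays open and untested beside it.

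The cholesterol synthesis list was lower in old libraries in all 23 members, and of 100 splits of the libraries the real one gave its lowest camera p, 5.1e-13 against 2.0e-11 for the next, and its largest mean difference, -0.26 against 0.25 in size. So 1 split of 100 gave a p as low, but 49 splits called the list, and since it was singled out of 37 after the values were seen, 100 splits are too few to say whether chance can be excluded. Different cell cycle levels are argued against as the whole cause, since the median stayed at -0.21 with the cell cycle level as a covariate against -0.26 without. The splits with a camera p as low as the real one numbered 2 for the ribosomal, 5 for the circadian, 11 for the oxidative phosphorylation and 66 for the cell cycle list. With an estimated correlation the cholesterol list was not called, so the shift in relation to other genes remains a hypothesis.

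For the number of genes changed, 3 of 100 splits gave 2 or more, the real one among them, while 96 called 0. The highest other split called 694 genes and the next 515. A count of 2 was thus seldom reached by other groupings, below a bound of 5 of 100 splits that was set after the results were seen. The 2 other splits that reached it called far more genes, so this count does not exclude chance. Splits that call so many genes point to a structure of the libraries that is not age. Both put young replicate 6 and old replicates 2 and 3 on one side, but of the 15 splits that did so 12 called 0 genes and 1 called 1, so this shared side alone does not account for the calls. The split with 694 genes followed the first principal component, parting libraries at -12.7 or lower from those at -9.51 or higher. The split with 515 nearly did so, with young replicate 4 in place of old replicate 6. With young replicate 4 in place of young replicate 5 instead, 1 gene was called. For the number of lists called, 79 of 100 splits called 5 or more and the highest other called 21, so chance cannot be excluded.

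Old replicate 6 held 5 outlying values, with Ly6c2 at 22.5 CPM, Il7r at 304 CPM, Atp6v0d2 at 335 CPM, Gpnmb at 19302 CPM and Xist at 501 CPM, each above the other old libraries. Young replicate 5 was high in Bst2 (726 CPM) and Cd74 (2646 CPM) and low in genes with a count (17179). Young replicate 3 was high in Clec1a (2.32 CPM) and Tnfsf13 (11.9 CPM) and low in Chchd7 (18.5 CPM). Single values stood out for Cd68 in old replicate 1 (2912 CPM, high), Cyp51 in old replicate 2 (47.4 CPM, high), Sqstm1 in young replicate 1 (756 CPM, low) and Ly6c2 in young replicate 2 (1.502 CPM, high).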

How the results depend on the processing

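Leaving out young replicate 6 and old replicates 2 and 3 together, the cell cycle covariate, and a term for replicate numbers 4 and 5, were chosen after seeing the data, and the other alternatives before. Against 2 genes changed (2 higher, 0 lower), the count was 4 with no low-count filter (1 lower), 15 with DESeq2 (10 higher, 5 lower), 4 with limma voom and quality weights (1 lower), 5 with 1 surrogate variable (4 higher, 1 lower), 5 with the cell cycle covariate (4 higher, 1 lower) and 1 at an adjusted p below 0.01 (1 higher). With the 3 libraries left out there was 1 gene higher and 2 lower. Leaving out 1 library gave 1 to 5 genes, 1 to 5 higher and 0 to 1 lower, with 5 without young replicate 3, 1 without young replicate 4, where Gdf3 had an edgeR adjusted p of 0.057, and 1 lower, Plxdc2, without young replicate 6. Both genes were called under each other scaling, and Bmpr1a was called in all 27 alternatives followed, while Gdf3 was not called in 2, with log2 fold changes of 1.05 and 0.96 there against 1.07. Gdf3 was called with any single library other than young replicate 4 left out, and why these 2 calls were lost was not tested. All 458 fold changes of 17 genes kept their direction, 28 of them newly past the threshold, 9 of these for Cpne8. Against 5 lists called there were 0 with an estimated correlation, 0 with fry and 4 to 8 with 1 library left out, 8 without young replicate 5. The cell cycle list turned upward without young replicate 6 (adjusted p = 0.41, within 1.5e-05 to 0.50 over single libraries left out) and with the cell cycle covariate (0.98), which removes that list by construction. Cholesterol synthesis, oxidative phosphorylation and ribosomal calls were each lost in 2 of 22 settings, the estimated correlation and fry, while the circadian call was lost in 8 and the cell cycle call in 6, besides the 2 in which it turned. With the cell cycle covariate interferon-stimulated genes were called lower (camera adjusted p = 1.3e-09), though not with an estimated correlation (adjusted p = 0.89). The lower total of old libraries passed without any 1 library (-2.47 to -1.83 M). The measures that did not pass changed sign without single libraries: the assigned share ran from -0.114 to 0.198 points, the mitochondrial share from -0.0059 to 0.0556, the share of the 100 most counted genes from -0.597 to 0.249, and genes with a count from -85.4 to 12.5. The share of the 20 most counted genes differed by 0.111. As a replicate block the shared numbers gave 4 genes, 4 higher, and 6 lists. Neutrophil markers were the list added (camera adjusted p = 0.0026), though not with an estimated correlation (adjusted p = 0.96). The numbers were not taken to pair the libraries. Same-numbered libraries correlated above 0.1 for numbers 1, 2, 4 and 5 (0.31, 0.12, 0.38 and 0.39) and not for 3 and 6 (0.02 and -0.17). Young and old libraries of numbers 4 and 5 correlated best among themselves, and a term for these 2 numbers gave 3 genes, all higher, and 6 lists. The list added was again neutrophil markers (camera adjusted p = 0.049), though not with an estimated correlation (adjusted p = 0.99). A sex covariate was not run, since all libraries were of one kind. In counts simulated at this depth and spread (biological coefficient of variation 21.7%), 42% of genes changed 1.5-fold were recovered, and 60% of those of at least 5 CPM. These counts were drawn independently for each gene, unlike the real ones, and depth alone was not varied.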

Other observations

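All tests in this part were chosen after the values were seen. Id1 and Id3, 2 direct targets of BMP signalling, were higher in old macrophages once young replicate 6 was set aside, in the same libraries where the BMP receptor gene Bmpr1a was higher. Id3 lay between 8.72 and 19.3 CPM in the other 5 young libraries and between 24.4 and 59.3 CPM in the old ones, and Id1 between 0.353 and 1.14 CPM and between 1.31 and 3.07 CPM. The highest old values of Id1, Id3, Smad6 and Bambi were in old replicates 2 and 3, the old libraries with the highest cell cycle means, with Id3 at 59.3 and 58.4 CPM there against 24.4 to 27.3 CPM in the other 4. Neither passed the threshold over all genes without that library (log2 fold change 1.49 for Id3 and 1.34 for Id1, edgeR adjusted p 0.78 for both).

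The hypothesis that BMP signalling may be stronger with the higher Bmpr1a level was tested on 7 measured target genes (Id1, Id2, Id3, Smad6, Smad7, Bambi and Hey1), a list written after Id1, Id3 and Smad6 had been seen. Over all 12 libraries their mean log2 CPM differed by 0.17 (two-sided exact permutation p = 0.78). Without young replicate 6 it differed by 0.57, with 5 of 6 old libraries above the highest young one (exact permutation p = 0.0087, adjusted p = 0.035 over the 4 tests run). For the 4 targets not looked at before, the difference was 0.07 over all libraries (exact permutation p = 0.64) and 0.19 without young replicate 6 (exact permutation p = 0.056, adjusted p = 0.11). The hypothesis thus stays open, because several targets were highest in the 3 libraries that stand apart in cell cycle level, and because the result rests on leaving out 1 library, in which the targets other than Hey1 were highest of all 12 while Bmpr1a stood at 0.970 CPM.

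Gm47283, a gene annotated at positions 90784738 to 90816465 of chromosome Y and picked after its values were seen, split the libraries by replicate number and not by age. It had 2 and 10 counts in young replicates 4 and 5 and 2 and 8 counts in old replicates 4 and 5, against 220 to 586 counts in the other 8 libraries. Since Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every library, the counts of Gm47283 do not show a Y chromosome in any of them. Where these reads come from was not tested. No label says what libraries of these numbers share.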
